A study of Mus musculus with 63 samples.

How the data were processed

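The data are RNA-seq profiles of heart from 63 mice of the 8 Diversity Outbred founder strains, labelled 129 (n = 8), AJ (n = 8), B6 (n = 8), Cast (n = 7), NOD (n = 8), NZO (n = 8), PWK (n = 8) and WSB (n = 8). The labels give the diet (high fat and high sugar, 45% fat), the tissue and, in the titles, a number per library. Sex and age are not in the labels used here. Nothing beyond the identifiers in the titles says that the replicates are separate animals, and each library was taken as 1 mouse. Per the labels, RNA came from frozen, pulverised tissue, polyA RNA was selected with oligo-dT beads, and ERCC spike-in RNA was added. Spike-in counts, other tissues and sequence reads were not analysed here. Strand use in counting, the aligner and the counter are not given in the sources used here.

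The deposited count table holds estimated counts per gene (expected counts, not normalised) that the authors assigned to genes of GRCm38. Of its values 18.4% are not whole within a tolerance of 1e-06. It lists 19220 genes, each with a value above 0 in at least 32 of the 63 libraries, so genes seen in fewer libraries are not in it. The deposited variance-stabilised table holds log2 values that the authors made with DESeq2 from the same genes and libraries, with zero counts at 6.55. It served only as an alternative. Gene positions are from the deposited annotation, and gene types from GENCODE M21, which matched 19139 of the genes and not 81. B6 is the strain of the reference genome GRCm38, and loss of reads from other strains to sequence variants was not tested. Total counts ran from 21.8 M to 42.9 M per library, so a gene with 3 counts over 8 libraries of PWK lies at 0.0108 CPM. Intervals and floors cover counting error only.

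Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0 and the package data.table (version 1.17.8). Genes with low counts were left out by filterByExpr with a minimum count of 10, which kept 16425 genes and left out 2795. Libraries were scaled by TMM (factors 0.828 in 129_9 to 1.16 in WSB_1), and CPM values are on that scale. A single edgeR quasi-likelihood fit (robust) with a coefficient per strain and 55 residual degrees of freedom gave the test over all strains, the 28 pairwise tests and each strain against the unweighted mean of the other 7. Log2 fold changes average the other strains on the log scale, while the CPM printed for the other strains is the mean of their 7 means. Wild-derived against classical strains was tested by limma (trend and robust) on the 8 strain means of log2 CPM with a prior count of 2. Adjusted p-values are Benjamini-Hochberg, and 0.05 was the threshold. The mitochondrial share was compared by a two-sided permutation test with 1e+05 resamples.

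The design, the gene lists, the alternatives other than leaving out libraries or reference strains and summing copies, and the rule for naming genes were fixed before the data were examined. The rule named, for each strain, the 5 largest positive and 5 largest negative log2 fold changes among genes past the test with a mean log2 CPM of at least 1 and every library of the strain above, or below, every library of the others. For all strains it named the 10 genes with the widest range of strain means and a mean log2 CPM of at least 3, and for wild-derived strains up to 10 genes per direction with no overlap of strain means. Symbols of the forms Gm and digits, or ending in Rik or -ps, clone names, Xist and Y-linked genes were counted and not named. For each list past the test in a strain it named up to 3 members per direction, and Nnt, H2-Ea and Glo1 always. Some genes that the rule names are not reported here.

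The 42 lists (691 genes, 644 measured, 44 in more than 1 list) cover metabolism, stress, immunity, matrix, the heart muscle and markers of cell types. Lists with at least 3 measured members were tested by limma's camera with a preset correlation of 0.01 over all lists and strains (328 tests), with camera at an estimated correlation and fry beside it. The limit of 3 members was set after the data were read. Members were counted with adjustment over all genes, and the count adjusted over the list alone is printed where it differs. Near-identical copies were sought by aligning all transcripts of named and wide-ranging genes to all transcripts (at least 95% identity over at least 50% of the shorter). The procedure was tested on simulated data. In the WSB contrast, simulated changes of 0.5 log2 units were recovered in 86% of genes and changes of 1 unit in 100%. There were 8 false calls among 15961 unchanged genes. The changed genes had a mean log2 CPM of at least 1, only WSB differed, and no simulated library stood apart. These rates therefore do not cover genes at lower levels or libraries that stand apart. For wild-derived strains 62% of changes of 1 unit and 78% of changes of 2 units were recovered. Alternatives included DESeq2 size factors, DESeq2 tests, limma on the variance-stabilised values, other filters and thresholds, covariates, B6 as the reference, a replicate block and leaving out libraries.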

Results

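Heart RNA was compared among the 8 founder strains of the Diversity Outbred mouse population, named by the labels as 129, AJ, B6, Cast, NOD, NZO, PWK and WSB. Each strain had 8 libraries, apart from Cast with 7, and all 63 came from mice on a high-fat, high-sugar diet with 45% fat. Libraries are named by strain and replicate number, so WSB_1 is replicate 1 of WSB. Total estimated counts ran from 21.8 M in Cast_2 to 42.9 M in AJ_1, with a median of 30.4 M. Genes of the mitochondrial genome took 29.2 ± 1.5% (SD, n = 8) of the counts in B6 and 27.0 ± 1.5% (SD, n = 8) in 129, against 17.8 ± 1.12% (SD, n = 8) in PWK. These shares differed among the strains beyond the spread between mice (two-sided permutation test over all 63 libraries, p = 1e-05, the smallest that 1e+05 resamples can give).

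A pair of genes with well-known strain differences served as a check of the labels. Nnt, which encodes the mitochondrial transhydrogenase, was lowest in B6 at 442 ± 35.5 CPM (SD, n = 8), and the other strains lay between 543 and 846 CPM. Glo1, which encodes glyoxalase, was highest in AJ at 266 ± 6.1 CPM (SD, n = 8), and the other strains lay between 74.2 and 157 CPM. In log2 fold change against the mean of the other strains, Nnt in B6 was -0.66 ± 0.11 (SE, adjusted p = 1.01e-06) and Glo1 in AJ was 1.45 ± 0.04 (SE, adjusted p = 6.44e-38). In AJ_3 Nnt was at 626.6 CPM, below the other AJ libraries, and in WSB_1 it was at 117.9 CPM. H2-Ea was not analysed here.

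**Figure D1:**
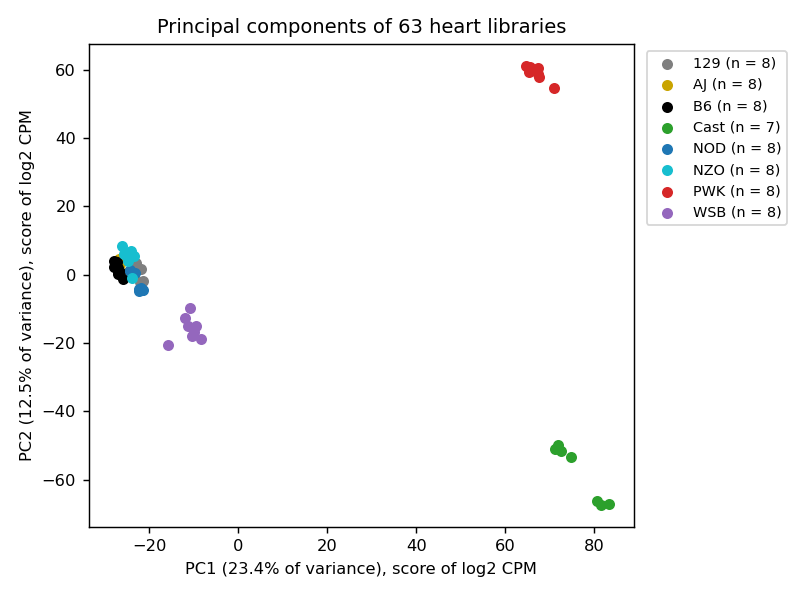
Scores of the 63 heart libraries on the first principal components of log2 CPM (PC1, 23.4% of the variance, on the x axis, and PC2, 12.5%, on the y axis), 1 point per library and coloured by strain. The Cast, PWK and WSB libraries lie apart from the other strains, and Cast_1, Cast_5 and Cast_6 lie apart from the other Cast libraries.

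The genes with the widest range of strain means included Ly6c1, Fam213b, Iigp1 and Hba-a1, together with ribosomal protein pseudogenes. Ly6c1, which encodes a surface antigen of leukocytes and endothelium (ENSMUSG00000079018, chromosome 15, 75044018 to 75048830, GRCm38), was at 79.2 ± 27.1 CPM (SD, n = 8) in NZO and had 2 counts over all 8 WSB libraries. Neither Fam213b, which encodes a prostamide synthase, nor Iigp1, which encodes an interferon-induced GTPase, had a count in any Cast library, while the other strains lay between 27.5 and 44.4 CPM for Fam213b and between 11.8 and 42.9 CPM for Iigp1. The haemoglobin gene Hba-a1 was at 3.81 CPM or less in 129, AJ, B6 and Cast and at 1257 ± 497 CPM (SD, n = 8) in PWK. Its near-identical copy Hba-a2 was at 176 CPM in PWK and 570.0 to 1380.2 CPM elsewhere, and their sum ranged over 1.78 log2 units, so the level of Hba-a1 alone is uncertain.

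Most of the other wide ranges lay in genes whose reads could be divided between copies. The strain means of Rpl9-ps6 spanned 10.5 log2 units, with 12 counts over the Cast libraries, but Rpl9-ps6, Rpl9 and Rpl9-ps7 summed to between 130.1 and 166 CPM in every strain. Alone, Rpl19-ps11 spanned 10, Rpl27-ps3 9.21, Rpl17-ps8 8.62 and Eif4a-ps4 9.64 log2 units, while their sums with copies spanned 0.26, 0.38, 0.23 and 0.30. mt-Co2 spanned 8.73 log2 units alone and 1.04 when summed with Gm13341 and Gm28661. Ly6c1 also shares sequence with Ly6a, which was at 88 CPM in WSB and 34.5 to 71.6 elsewhere. The sum of Ly6c1 and Ly6c2 spanned 7.95 log2 units, so Ly6c2 does not hold the missing counts. The sum with Ly6c2 and Ly6a spanned 0.806 log2 units, so the level of Ly6c1 alone is uncertain. These 10 genes had the widest ranges among the 7916 past the test over all strains with a mean log2 CPM of at least 3. Genes with symbols that the naming rule leaves out were set aside before this ranking.

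**Figure D2:**
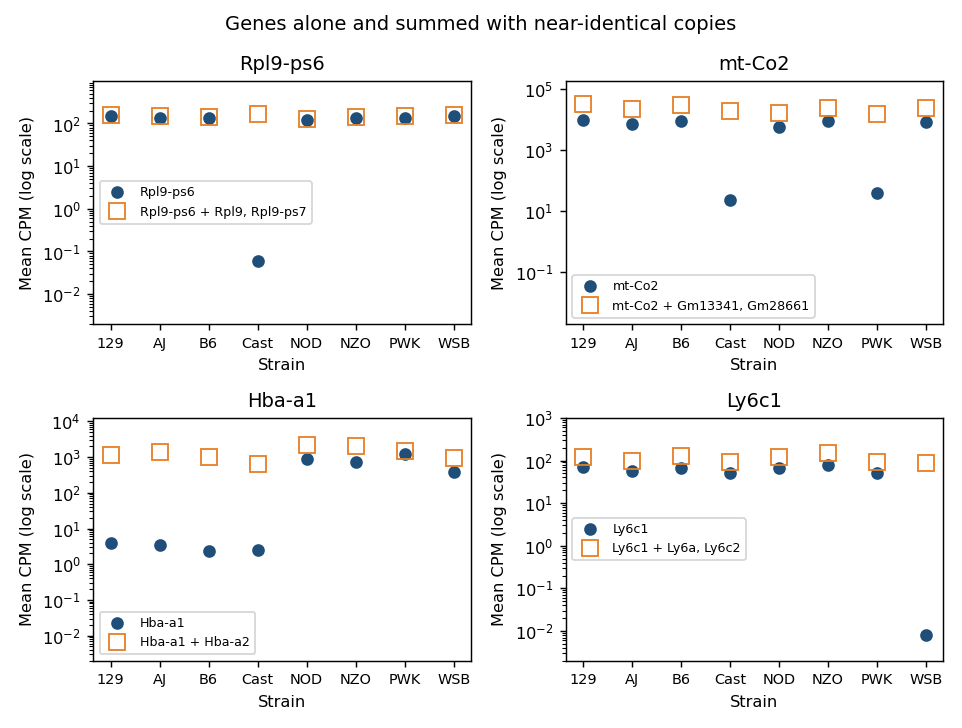
Mean CPM per strain (y axis, log scale) of Rpl9-ps6, mt-Co2, Hba-a1 and Ly6c1 alone (filled circles) and summed with their near-identical copies (open squares), for each strain on the x axis. The sums of Rpl9-ps6 lie between 130.1 and 166 CPM in every strain, and those of Ly6c1 with Ly6c2 and Ly6a between 88.2 and 154 CPM.

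Most genes differed among the strains. Of 16425 tested genes, 14837 (90.3%) differed among the strains in edgeR's quasi-likelihood test at an adjusted p of 0.05, and 6312 of these had strain means at least 1 log2 unit apart. The median share of a gene's variance lying between strains (adjusted R squared of log2 CPM on strain) was 0.443, and it was over 0.5 for 42.7% of genes. Between a pair of strains 3506 genes differed at the lowest (129 and B6) and 9365 at the highest (Cast and NZO), with a median of 7098.5 over the 28 pairs. Pairs with Cast or PWK had a median of 8767 and the others 4782.

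**Figure D3:**
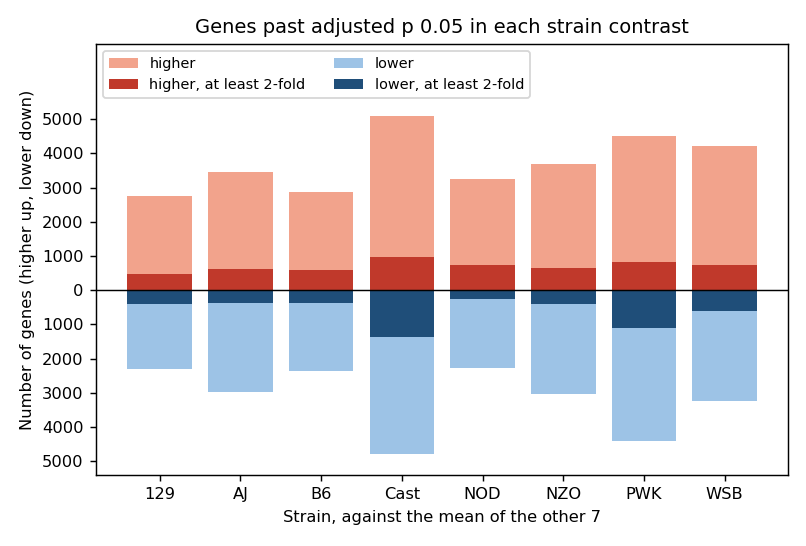
Number of genes past an adjusted p of 0.05 in each strain against the mean of the other 7 (y axis, higher genes above 0 and lower genes below), for each strain on the x axis. Darker bars count genes at least 2-fold apart, and Cast (9886 genes) and PWK (8905 genes) have the tallest bars.

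The 129 hearts had more RNA of an ion channel gene and of some genes of energy metabolism. Kcnj14, which encodes an inward-rectifier potassium channel (ENSMUSG00000058743, chromosome 7, 45816461 to 45824756), was at 49.1 ± 8.71 CPM (SD, n = 8) against 3.39 over the other strains, a log2 fold change of 4.40 ± 0.12 (SE, adjusted p = 2.85e-39). The kinesin gene Kif5c was at 13.2 ± 1.91 CPM (SD, n = 8) against 2.02, a log2 fold change of 2.85 ± 0.10 (SE, adjusted p = 4.22e-34). The junction gene Plekha7 (2.25 ± 0.08), Sh3rf2 (1.58 ± 0.11) and the oxysterol-binding Osbpl3 (1.29 ± 0.06) were also higher, in log2 fold change ± SE. The exchange factor gene Arhgef19 was lower at 2.75 ± 0.663 CPM (SD, n = 8) against 16.2 (-2.42 ± 0.12), as were Cep126 (-1.97 ± 0.15) and Ttc38 (-1.82 ± 0.10). Jmjd7 (-2.26 ± 0.15) was lower also when summed with its near-identical copy (-2.40 ± 0.12). Cep83os (-2.62 ± 0.13) is divergent from its neighbour and uncertain.

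Some metabolic and contractile lists passed in 129 by camera, but the first 2 below did not in fry (adjusted p = 0.0616 and 0.12). Random strain labels gave a median of 79 camera calls, where the real labels gave 46. A camera call alone, here or in the strains below, therefore does not show that a list differs. For fatty acid oxidation, 6 of 23 measured members were higher and 17 did not pass the gene test, with Acadm (0.45 ± 0.08), Acaa2 (0.31 ± 0.06) and Eci1 (0.29 ± 0.07) as the largest (camera adjusted p = 0.0271, and adjusted p = 0.997 with an estimated correlation). For the TCA cycle and pyruvate entry, 8 of 25 measured members were higher, 1 lower and 16 did not pass the gene test, with Idh2 (0.32 ± 0.04), Fh1 (0.23 ± 0.04) and Cs (0.22 ± 0.07) higher and Mpc1 (-0.20 ± 0.06) lower (camera adjusted p = 0.0356, and adjusted p = 0.997 with an estimated correlation). That call was lost without 129_3 (adjusted p = 0.0728), 129_6 (0.0645), 129_9 (0.0505), without Cast_1, Cast_5 and Cast_6 (0.0585), without genes on chromosomes X, Y and MT (0.0622) or with a mean log2 CPM of at least 1 as the filter (0.0514). Sarcomere genes were higher too: 8 of 20 measured members were higher, 1 lower and 11 did not pass the gene test (10 higher and 2 lower when adjusted over the list alone), with Actc1 (0.48 ± 0.09), Tpm1 (0.43 ± 0.05) and Mybpc3 (0.35 ± 0.06) higher and the small heat shock protein gene Cryab (-0.29 ± 0.07) lower (camera adjusted p = 0.0166, and adjusted p = 0.997 with an estimated correlation). Of the genes on the mitochondrial genome, 12 of 13 measured members were higher and 1 did not pass the gene test, with mt-Nd1 (0.63 ± 0.05) as an example (camera adjusted p = 2.17e-12, and adjusted p = 0.533 with an estimated correlation). mt-Co2 and mt-Nd4l share reads with nuclear copies and are uncertain. With B6 as the reference Acadm, Acaa2, Idh2, Fh1, Cs, Mpc1, mt-Nd1, mt-Co2 and mt-Nd4l did not pass (adjusted p from 0.0672 to 0.971), and Mpc1 did not pass without Cast in the reference (0.08).

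In 129, 5071 genes passed the test, 2763 higher and 2308 lower, and 482 and 409 of these were at least 2-fold higher and lower. Every 129 library lay above all other libraries for 29 tested genes and below for 20, where chance would give less than 1 gene in any strain.

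In AJ the scaffold gene Baiap2l1 (ENSMUSG00000038859, chromosome 5, 144264526 to 144358112) was at 175 ± 15.6 CPM (SD, n = 8) against 13.5 over the other strains, a log2 fold change of 3.77 ± 0.08 (SE, adjusted p = 4.55e-45). Nppb, which encodes the natriuretic peptide BNP, was at 289 ± 58.6 CPM (SD, n = 8) against 81.4, a log2 fold change of 1.86 ± 0.16 (SE, adjusted p = 8.03e-15). The Wnt inhibitor gene Wif1 (1.99 ± 0.09), Sgip1 (2.01 ± 0.09) and AI506816 (3.61 ± 0.07) were higher as well, in log2 fold change ± SE, and AI506816 stayed higher when summed with its near-identical copy (2.50 ± 0.08). Dysf, which encodes the membrane repair protein dysferlin, was at 38.8 ± 2.04 CPM (SD, n = 8) against 125, a log2 fold change of -1.65 ± 0.06 (SE, adjusted p = 4.69e-32). Col4a6, a basement membrane collagen gene, was at 0.127 ± 0.0804 CPM (SD, n = 8) against 6.65 (-5.68 ± 0.24), and Scarf1 (-1.76 ± 0.11), Iah1 (-1.60 ± 0.12) and Trabd2b (-1.58 ± 0.07) were lower.

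Most measured members of the B cell, antigen presentation and glucose lists were higher in AJ. For B and plasma cell markers, 12 of 12 measured members were higher, with Ighm at 47.7 ± 47.1 CPM (SD, n = 8) as an example (camera adjusted p = 0.00652, and adjusted p = 0.997 with an estimated correlation). Igkc, chosen after its values were seen, was at 0.918, 1.85 and 0.503 CPM in AJ_2, AJ_7 and AJ_8 and at 17 to 57.9 in the other AJ libraries. The adipocyte genes Adipoq (0.765, 1.64 and 1.80 against 3.84 to 10.7 CPM) and Cfd (0.949, 1.09 and 1.83 against 10.3 to 22.7) split the libraries in the same way. For MHC class I and antigen processing, 12 of 15 measured members were higher, 2 lower and 1 did not pass the gene test, with Nlrc5 (1.29 ± 0.25) higher and H2-T23 (-0.80 ± 0.16) lower (camera adjusted p = 0.00698, and adjusted p = 0.997 with an estimated correlation). H2-Q6 (2.40 ± 0.22), H2-Q7 (1.78 ± 0.24) and H2-T22 (-2.15 ± 0.16) have near-identical relatives. Summed with these, H2-Q6 (1.96 ± 0.22), H2-Q7 (2.01 ± 0.22) and H2-T23 (-0.63 ± 0.15) kept their direction, and H2-T22 did not (0.44 ± 0.12), so H2-T22 alone is uncertain. H2-Q6 and H2-Q7 were lower than B6 where B6 was the reference, and Nlrc5 did not pass there (adjusted p = 0.505). For glucose uptake and glycolysis, 13 of 24 measured members were higher, 1 lower and 10 did not pass the gene test (14 higher and 1 lower when adjusted over the list alone), with Pygb (0.94 ± 0.09), Gapdh (0.64 ± 0.08) and Slc2a1 (0.62 ± 0.10) higher and Pfkp (-0.68 ± 0.09) lower (camera adjusted p = 0.00481, and adjusted p = 0.997 with an estimated correlation). Summed with its near-identical copies Gapdh was at 0.59 ± 0.08. Pygb (adjusted p = 0.142) and Pfkp (0.473) did not pass against B6 alone. For oxidative stress and glutathione, 14 of 27 measured members were higher and 13 did not pass the gene test, with Nqo1 (0.57 ± 0.07), Srxn1 (0.50 ± 0.07) and Gstm2 (0.48 ± 0.07) the largest (camera adjusted p = 0.0278, and adjusted p = 0.997 with an estimated correlation). In total 6438 genes passed the test in AJ, 3462 higher and 2976 lower. Of these 629 and 387 were at least 2-fold apart. For 53 tested genes every library of the strain lay above all other libraries, and for 21 below.

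B6 hearts had higher levels of interferon and antigen presentation genes and lower levels of stress genes. B6 is also the strain of the reference genome, and whether other strains lose reads to variants in the higher genes was not tested. Of the interferon response list, 24 of 26 measured members were higher and 2 did not pass the gene test, with Oas2 at 16 ± 4.13 CPM (SD, n = 8) against 5.24 over the other strains, a log2 fold change of 1.92 ± 0.14 (SE, adjusted p = 1.39e-18). Iigp1 (2.60 ± 0.32) was higher too, but Cast, at 0 counts, sets most of that value, which was 0.81 ± 0.24, adjusted p = 0.00747 without Cast in the reference. Ifit3 (1.79 ± 0.15) was 1.54 ± 0.15 summed with its copy (camera adjusted p = 1e-11, and adjusted p = 0.791 with an estimated correlation). For MHC class II, 7 of 8 measured members were higher and 1 did not pass the gene test, with H2-Eb1 (2.93 ± 0.19), H2-Ab1 (1.86 ± 0.19) and H2-Aa (1.5 ± 0.22) the largest (camera adjusted p = 4.18e-05, and adjusted p = 0.837 with an estimated correlation). For MHC class I and antigen processing, 13 of 15 measured members were higher and 2 did not pass the gene test, with H2-Q7 (3.23 ± 0.20), H2-Q6 (3.22 ± 0.20) and H2-T22 (1.09 ± 0.11) higher when summed with their relatives (camera adjusted p = 1.01e-08, and adjusted p = 0.837 with an estimated correlation). For the mitochondrial genome, 12 of 13 measured members were higher and 1 did not pass the gene test (13 higher when adjusted over the list alone), and the largest named members have nuclear copies. Summed with these, mt-Co2 was at 0.48 ± 0.06, mt-Nd4l at 0.54 ± 0.08 and mt-Nd3 at 0.93 ± 0.07 (camera adjusted p = 9.39e-17, and adjusted p = 0.248 with an estimated correlation). Among cardiac stress and fetal genes, 7 of 15 measured members were lower and 8 did not pass the gene test, with Acta1 (-2.04 ± 0.22) and Ankrd1 (-1.17 ± 0.14) lower (camera adjusted p = 0.000844, and adjusted p = 0.533 with an estimated correlation). Myh7 (-1.38 ± 0.28) has the copy Myh6. Their sum, 29480 CPM in B6, is nearly all Myh6 and cannot tell whether Myh7 changed. Alone, Myh7 was at 81.7 to 212 CPM in B6 and 93.3 to 206 in 129, AJ and WSB. It was at 898 to 8076 CPM in Cast, 322 to 2406 in PWK and 374 to 796 in NOD, which raise the reference mean. Among heat shock genes and chaperones, 11 of 14 measured members were lower and 3 did not pass the gene test, with Dnajb1 (-0.85 ± 0.24) and the near-identical pair Hspa1b (-3.01 ± 0.67) and Hspa1a (-2.71 ± 0.59) lower, the pair at -2.88 ± 0.62 in sum (camera adjusted p = 0.00114, and adjusted p = 0.997 with an estimated correlation).

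Among B6 genes with no near-identical copy, Pttg1, which encodes securin (ENSMUSG00000020415, chromosome 11, 43420250 to 43426251), was at 40.3 ± 2.57 CPM (SD, n = 8) against 1.8, a log2 fold change of 4.53 ± 0.07 (SE, adjusted p = 4.34e-55). Cyfip2, which encodes a regulator of actin assembly, was at 238 ± 8.82 CPM (SD, n = 8) against 17.6, a log2 fold change of 4.42 ± 0.08 (SE, adjusted p = 2.51e-48). Rab6b (3.73 ± 0.11) and Pkd2l2 (2.10 ± 0.08) were higher too, while Gvin1 (4.75 ± 0.16) has copies and was at 1.93 ± 0.13 summed with them. The glycosyltransferase gene Gcnt1 (-2.42 ± 0.14), Hddc3 (-2.29 ± 0.08), Tmem37 (-2.13 ± 0.13), Wdfy1 (-1.92 ± 0.06) and Kbtbd12 (-1.82 ± 0.08) were lower, in log2 fold change ± SE, but Hddc3 shares sequence with other genes and was at -0.69 ± 0.04 summed with them. In B6, 5225 genes passed the test, 2871 higher and 2354 lower. Of these 604 and 375 were at least 2-fold apart. For 44 tested genes every library of the strain lay above all other libraries, and for 19 below.

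Cast hearts had lower levels of interferon, antigen presentation and fibroblast genes. Whether variants against the reference genome, which is that of B6, lower such counts in Cast, PWK or WSB was not tested. Iigp1 had 0 counts over the 7 Cast libraries and was at least 2010.1-fold lower than the mean of the other strains, taken at a floor of 3 counts over the group. Fam213b (ENSMUSG00000029059, chromosome 4, 154895504 to 154899135) also had 0 counts and was at least 2457-fold lower. For the interferon response list, 2 of 26 measured members were higher, 20 lower and 4 did not pass the gene test (3 higher and 20 lower when adjusted over the list alone), with Ifi44 (-5.22 ± 0.38) and Oas2 (-2.83 ± 0.25) lower (camera adjusted p = 0.000112, and adjusted p = 0.997 with an estimated correlation). For MHC class II, 8 of 8 measured members were lower, with H2-Ab1 (-2.58 ± 0.32), H2-Aa (-2.43 ± 0.34) and Cd74 (-1.97 ± 0.32) the largest (camera adjusted p = 0.00398, and adjusted p = 0.997 with an estimated correlation). For MHC class I and antigen processing, 12 of 15 measured members were lower and 3 did not pass the gene test (13 lower when adjusted over the list alone), with H2-K1 at 13.5 ± 3.03 CPM (SD, n = 7) against 52.5 over the other strains (camera adjusted p = 0.00366, and adjusted p = 0.997 with an estimated correlation). Summed with their relatives, H2-Q6 (-2.34 ± 0.37), H2-Q7 (-2.48 ± 0.37) and H2-K1 (-1.45 ± 0.18) were lower too.

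Matrix genes were lower as well, and their level differed among the Cast libraries. For extracellular matrix and fibrosis, 3 of 27 measured members were higher, 20 lower and 4 did not pass the gene test (4 higher and 20 lower when adjusted over the list alone), with Postn (-1.70 ± 0.14), Col6a1 (-1.28 ± 0.15) and Comp (-1.20 ± 0.15) lower (camera adjusted p = 0.00366, and adjusted p = 0.997 with an estimated correlation). For fibroblast markers, 12 of 12 measured members were lower, with Pi16 (-1.90 ± 0.16), Col3a1 (-1.04 ± 0.22) and Col1a2 (-0.96 ± 0.12) lower (camera adjusted p = 2.45e-05, and adjusted p = 0.791 with an estimated correlation). Cast_1, Cast_5 and Cast_6 had 36.3, 24.1 and 18.8 CPM of the collagen gene Col1a1 against 96.0 to 122 in the other Cast libraries. The same libraries had 363, 235 and 256 CPM of Fkbp5, a glucocorticoid-induced gene, against 54.0 to 107. The neutrophil gene S100a9 was at 7.96 CPM in Cast_5 and 11.6 in Cast_6. Lcn2, a member of the glucocorticoid response and acute inflammation lists, was at 36.6 and 29.7 CPM there. Both genes were chosen after their values were seen. In the other Cast libraries S100a9 was at 2.37 CPM or less, and Lcn2 at 9.53 in Cast_1 and at 2.90 or less in the rest. Fkbp5 in Cast as a whole was at 167 ± 118 CPM (SD, n = 7) against 22.3, a log2 fold change of 2.96 ± 0.18 (SE, adjusted p = 6.56e-21). For the glucocorticoid response list, 10 of 14 measured members were higher and 4 did not pass the gene test, with Mt2 (2.28 ± 0.25) and Klf15 (1.08 ± 0.13) next (camera adjusted p = 0.0319, and adjusted p = 0.997 with an estimated correlation). That call was lost without Cast_1 (adjusted p = 0.0804) and without Cast_1, Cast_5 and Cast_6 (0.298), and with a mean log2 CPM of at least 1 as the filter (0.0752). Lox (1.21 ± 0.16) was higher with all 7 libraries but not without Cast_1, Cast_5 and Cast_6 (0.09, adjusted p = 0.674). Thbs1 (0.42 ± 0.19, adjusted p = 0.0492) lost its call under 8 alternatives (adjusted p from 0.0503 to 1), and also without Cast_6 (adjusted p = 0.116) or Cast_8 (0.0776), or without 129, B6 or WSB in the reference (0.0725, 0.0957 and 0.0743).

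**Figure D4:**
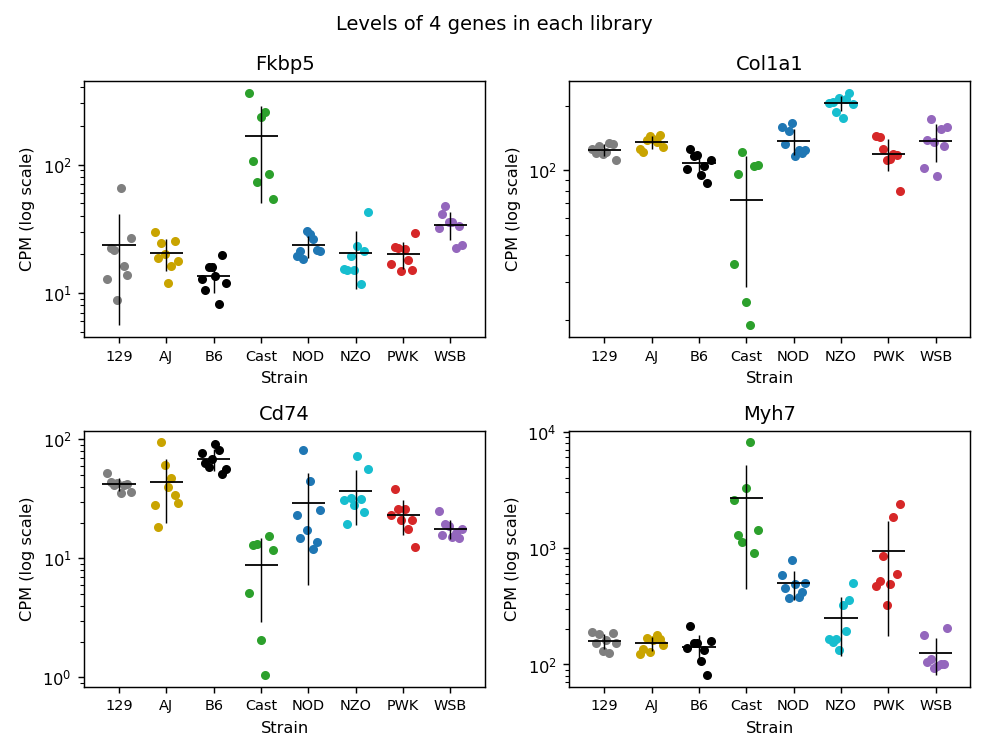
CPM (y axis, log scale) of Fkbp5, Col1a1, Cd74 and Myh7 in each library, by strain on the x axis, with the mean (horizontal line) and SD (vertical line). Within Cast, Cast_1, Cast_5 and Cast_6 have Fkbp5 at 363, 235 and 256 CPM and Col1a1 at 36.3, 24.1 and 18.8 CPM. Myh7 is at 2565, 3288 and 8076 CPM in these libraries and at 898 to 1430 CPM in the other Cast libraries.

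Further lists and genes set Cast apart. Of erythroid markers, 7 of 9 measured members were lower and 2 did not pass the gene test (1 higher and 8 lower when adjusted over the list alone), with Slc4a1 (-2.87 ± 0.36) lower and Hba-a1 at -1.10 ± 0.18 summed with Hba-a2 (camera adjusted p = 0.00404, and adjusted p = 0.997 with an estimated correlation). Hba-a1 alone did not pass against B6 alone (adjusted p = 0.818). Of Schwann cell and neuron markers, 6 of 9 measured members were lower and 3 did not pass the gene test, with Kcna1 (-1.09 ± 0.18) and Cdh19 (-1.06 ± 0.13) lower (camera adjusted p = 0.0128, and adjusted p = 0.791 with an estimated correlation), and that call was lost with a mean log2 CPM of at least 1 as the filter (adjusted p = 0.0616). Of oxidative stress and glutathione genes, 14 of 27 measured members were higher, 6 lower and 7 did not pass the gene test, with Gstm2 (1.56 ± 0.07) higher and Gstm5 (-0.78 ± 0.06), Gpx4 (-0.45 ± 0.08) and Gpx1 (-0.34 ± 0.10) lower (camera adjusted p = 0.0402, and adjusted p = 0.997 with an estimated correlation). That call was lost without Cast_5 (adjusted p = 0.0562), WSB_1 (0.0508) or Cast_1, Cast_5 and Cast_6 (0.132), and with that filter (0.0952). Gpx1 did not pass against B6 alone (adjusted p = 0.0675). Hmox1 was at 35.2 ± 42.2 CPM (SD, n = 7) against 6.69, with 129.6 CPM in Cast_1. Without Cast_1 its mean was 19.5 CPM and its log2 fold change 1.57 ± 0.12 (SE, adjusted p = 5.82e-18). Syt12, which encodes a synaptotagmin, was at 23.6 ± 10.3 CPM (SD, n = 7) against 2.5, a log2 fold change of 3.32 ± 0.11 (SE, adjusted p = 1.22e-36), and Itih4 (3.11 ± 0.16) and Proser2 (2.99 ± 0.10) were higher. Rpl9 was higher but shares reads with Rpl9-ps6. 9930111J21Rik1 (0 counts, at least 408-fold lower) and Tgtp2 (5 counts, 431-fold lower, with a counting interval of 185 to 1326) have copies and are uncertain, and without Cast_6 the mean of Tgtp2 was 0.0106 CPM. Without Cast_8 the mean of Rpl9-ps6 was 0.0205 CPM in place of 0.0603. In Cast 9886 genes passed the test, 5080 higher and 4806 lower. Of these 980 and 1359 were at least 2-fold apart. For 328 tested genes every library of the strain lay above all other libraries, and for 250 below. Without Cast_1, Cast_5 and Cast_6, 7724 genes passed, and 69.9% of the 9886 calls were kept.

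NOD hearts had more RNA of red cell and immediate early genes and less of ribosomal protein and mitochondrial genes. All erythroid markers were higher: 9 of 9 measured members were higher, with Slc4a1 (0.90 ± 0.20) as an example, while Hba-a1 and Hbb-bt (1.53 ± 0.18) have copies and were at 0.94 ± 0.15 and 0.77 ± 0.16 summed with them (camera adjusted p = 8.27e-06, and adjusted p = 0.791 with an estimated correlation). For immediate early genes, 13 of 21 measured members were higher and 8 did not pass the gene test (15 higher when adjusted over the list alone), with Fosb (1.62 ± 0.46), Fos (1.13 ± 0.31) and Nr4a1 (0.82 ± 0.25) the largest (camera adjusted p = 0.0113, and adjusted p = 0.997 with an estimated correlation). Fos was at 61.2 ± 35 CPM (SD, n = 8) against 29.8 over the other strains. For cytosolic ribosomal proteins, 23 of 37 measured members were lower and 14 did not pass the gene test (25 lower when adjusted over the list alone) (camera adjusted p = 1.75e-07, and adjusted p = 0.997 with an estimated correlation). Its largest members, Rpl19, Rpl27 and Rplp1 (-0.50 ± 0.09), have pseudogene copies. Summed with these, Rplp1 stayed lower (-0.50 ± 0.09) and Rpl19 and Rpl27 did not pass (adjusted p = 0.13 and 0.115). Without Cast in the reference Slc4a1 (0.0564) and Nr4a1 (0.0767) did not pass. Against B6 alone Rpl19, Rpl27, Rplp1, Fosb, Fos and Slc4a1 did not pass (adjusted p from 0.103 to 0.821). On the mitochondrial genome, 2 of 13 measured members were higher, 10 lower and 1 did not pass the gene test, with mt-Nd6 (-0.54 ± 0.11) lower (camera adjusted p = 0.000219, and adjusted p = 0.997 with an estimated correlation). mt-Nd5 (-0.55 ± 0.06), mt-Co3 (-0.49 ± 0.07), mt-Co2 and mt-Nd4l have nuclear copies, and summed with these they were at -0.55 ± 0.06, -0.48 ± 0.06, -0.53 ± 0.07 and -0.47 ± 0.09. Alone, mt-Co2 and mt-Nd4l lay above the log-scale mean of the other strains, which Cast or PWK pulled down, but below 5 and 6 of the other 7 strains and below B6 in the test.

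Map1a, which encodes a microtubule-associated protein (ENSMUSG00000027254, chromosome 2, 121289600 to 121310832), was at 158 ± 14.2 CPM (SD, n = 8) against 21.4 over the other strains in NOD, a log2 fold change of 2.95 ± 0.06 (SE, adjusted p = 9.93e-49). Ctsk, which encodes the protease cathepsin K, was at 0.128 ± 0.117 CPM (SD, n = 8) against 4.8, a log2 fold change of -5.10 ± 0.33 (SE, adjusted p = 9.25e-21). Hopx, which encodes a homeodomain protein of cardiac development, was at 55.7 ± 4.78 CPM (SD, n = 8) against 175, a log2 fold change of -1.58 ± 0.09 (SE, adjusted p = 4.64e-24). Tmem144 (1.86 ± 0.07), Kif6 (1.5 ± 0.09), Osbpl6 (1.46 ± 0.09) and Lrp3 (0.93 ± 0.06) were higher, and Hrasls (-2.84 ± 0.09) and Trim68 (-2.10 ± 0.08) lower, in log2 fold change ± SE. Hist2h2aa1 (-3.50 ± 0.13) has a copy and was at -1.36 ± 0.08 summed with it. In NOD 5527 genes passed the test, 3249 higher and 2278 lower. Of these 740 and 261 were at least 2-fold apart. For 23 tested genes every library of the strain lay above all other libraries, and for 20 below.

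NZO hearts had more RNA of matrix, fibroblast and immune genes and less of lipogenic genes. For extracellular matrix and fibrosis, 21 of 27 measured members were higher and 6 did not pass the gene test (22 higher when adjusted over the list alone), with Postn, which encodes periostin, at 73.6 ± 7.62 CPM (SD, n = 8) against 35.7 over the other strains, a log2 fold change of 1.22 ± 0.10 (SE, adjusted p = 1.13e-15). Col8a1 (1.19 ± 0.10) and Lum (0.89 ± 0.13) followed (camera adjusted p = 2.35e-07, and adjusted p = 0.791 with an estimated correlation). For fibroblast markers, 12 of 12 measured members were higher, with Col1a1 (0.82 ± 0.13) and Col3a1 (0.78 ± 0.18) higher beside Lum (camera adjusted p = 3.78e-06, and adjusted p = 0.791 with an estimated correlation). For de novo lipogenesis, 8 of 14 measured members were lower and 6 did not pass the gene test, with Scd4 (-3.18 ± 0.27), Scd1 (-1.51 ± 0.48) and Thrsp (-1.28 ± 0.25) lower (camera adjusted p = 0.00203, and adjusted p = 0.997 with an estimated correlation). Summed with Scd2, which matches part of it, Scd1 was at -1.28 ± 0.37. Among erythroid markers, 9 of 9 measured members were higher, with Slc4a1 (1.75 ± 0.19) higher, and Hba-a1 and Hbb-bt at 0.76 ± 0.15 and 0.76 ± 0.16 summed with their copies (camera adjusted p = 3.78e-06, and adjusted p = 0.791 with an estimated correlation). For the interferon response, 22 of 26 measured members were higher, 2 lower and 2 did not pass the gene test (23 higher and 2 lower when adjusted over the list alone), with Rsad2 (1.20 ± 0.11) higher as an example (camera adjusted p = 9.82e-05, and adjusted p = 0.997 with an estimated correlation). The values of Iigp1 (1.85 ± 0.37) and Ifi44 (1.20 ± 0.17) rested largely on Cast, which had 0 and 20 counts. Without Cast in the reference they were 0.04 ± 0.26, adjusted p = 0.916 and 0.47 ± 0.15, adjusted p = 0.0134, so no call is made for Iigp1. Xaf1 (-0.37 ± 0.12) did not pass without 129 (0.09) or PWK (0.411). Iigp1, at 78.5 CPM in NZO_5, did not pass limma on the deposited variance-stabilised values (adjusted p = 0.103), and Rsad2 was lower than B6 where B6 was the reference. For MHC class I and antigen processing, 11 of 15 measured members were higher and 4 did not pass the gene test, with Nlrc5 (1.16 ± 0.25) and H2-D1 (1.13 ± 0.13) higher. H2-T22 (1.16 ± 0.11) and H2-D1 (0.86 ± 0.14) were higher when summed with their relatives (camera adjusted p = 0.000543, and adjusted p = 0.997 with an estimated correlation). Against B6 alone Iigp1, Ifi44, Xaf1, Nlrc5, H2-D1, H2-T22 and Cfd did not pass (adjusted p from 0.0918 to 0.791).

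The complement and acute inflammation list of NZO rested on NZO_8. 17 of 22 measured members were higher, 1 lower and 4 did not pass the gene test, with C1s1 (1.11 ± 0.09) higher and Cfd (-2.29 ± 0.73) lower (camera adjusted p = 0.00404, and adjusted p = 0.997 with an estimated correlation). Cfd is also an adipocyte gene. Adipoq, chosen after its values were seen, lay between 0.288 and 5.86 CPM in NZO (-1.03 ± 0.55, SE, adjusted p = 0.13), and of 12 adipocyte markers 2 were higher and 2 lower (camera adjusted p = 0.910). Without NZO_8 the list did not pass (adjusted p = 0.0839). C3 was at 439 ± 453 CPM (SD, n = 8) against 213 over the other strains, with 1555 CPM in NZO_8. Without NZO_8 its mean was 279 CPM, and its log2 fold change was 0.44 ± 0.12 (SE, adjusted p = 0.00287) in place of 1.10 ± 0.17. C4b, at 1.31 ± 0.20 summed with its near-identical copy, had a mean of 89.3 CPM with NZO_8 and 57.3 without.

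Among single genes in NZO, Myom3, which encodes an M-band protein of the sarcomere (ENSMUSG00000037139, chromosome 4, 135759715 to 135815564), was at 27.9 ± 9.77 CPM (SD, n = 8) against 1.89, a log2 fold change of 3.96 ± 0.12 (SE, adjusted p = 3.4e-36). The endothelin gene Edn3 was at 21 ± 4.23 CPM (SD, n = 8) against 4.93, and Igf2 (1.62 ± 0.08) and Ssc5d (1.25 ± 0.08) were higher, as was Plac9b summed with its copies (2.29 ± 0.08). Pccb, which encodes a subunit of propionyl-CoA carboxylase, was at 28.6 ± 3.04 CPM (SD, n = 8) against 75.2, a log2 fold change of -1.34 ± 0.05 (SE, adjusted p = 6.88e-34). Tceanc2 (-3.47 ± 0.11), Fstl4 (-3.17 ± 0.19) and Ppp1r9a (-1.47 ± 0.07) were lower too. Zfp607 had 1 count, in NZO_1, over the 8 libraries, 911-fold lower, with a counting interval of 163 to 35965, and was at -4.75 ± 0.16 summed with its near-identical copy. In NZO 6739 genes passed the test, 3691 higher and 3048 lower. Of these 654 and 413 were at least 2-fold apart. For 58 tested genes every library of the strain lay above all other libraries, and for 25 below.

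PWK hearts differed in immune, detoxification and mitochondrial genes. Itgal, which encodes an integrin of leukocytes, was at 26.7 ± 4.19 CPM (SD, n = 8) against 2.67 over the other strains, a log2 fold change of 3.40 ± 0.19 (SE, adjusted p = 4.16e-23). Ifi27l2a, an interferon-induced gene, had 0 counts over the 8 libraries and was at least 829.6-fold lower than the mean of the other strains, at a floor of 3 counts over the group. For oxidative stress and glutathione, 6 of 27 measured members were higher, 17 lower and 4 did not pass the gene test, with Nnt (0.41 ± 0.10) and Gstm5 (0.29 ± 0.05) higher and Mt2 (-2.35 ± 0.38), Gsta3 (-2.27 ± 0.20) and Gstm2 (-1.59 ± 0.09) lower (camera adjusted p = 0.00404, and adjusted p = 0.837 with an estimated correlation). Gstp1 (0.32 ± 0.05) was higher, also summed with its copy (0.42 ± 0.05), and Gstm5 did not pass against B6 alone (adjusted p = 0.26). For MHC class I and antigen processing, 9 of 15 measured members were lower and 6 did not pass the gene test, with H2-Q4 (-1.70 ± 0.19) lower, as were H2-Q6 (-2.81 ± 0.36) and H2-Q7 (-2.82 ± 0.36) summed with their relatives (camera adjusted p = 0.0249, and adjusted p = 0.997 with an estimated correlation). For skeletal muscle markers, 5 of 6 measured members were lower and 1 did not pass the gene test, with Acta1 (-0.97 ± 0.20) and Ckm (-0.45 ± 0.05) lower (camera adjusted p = 0.0278, and adjusted p = 0.791 with an estimated correlation). That call was lost without a filter on low counts (adjusted p = 0.117), and Acta1 was higher than B6 where B6 was the reference. Of the mitochondrial genome, 12 of 13 measured members were lower and 1 did not pass the gene test, with mt-Atp8 (-0.99 ± 0.22) lower (camera adjusted p = 7.37e-08, and adjusted p = 0.791 with an estimated correlation). mt-Co2 (39.3 CPM) and mt-Nd4l (36.6 CPM) were at -0.58 ± 0.07 and -0.25 ± 0.09 summed with their nuclear copies.

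Rasef, which encodes a Rab-type GTPase (ENSMUSG00000043003, chromosome 4, 73714579 to 73790709), was at 28.9 ± 1.62 CPM (SD, n = 8) against 1.96 in PWK, a log2 fold change of 3.97 ± 0.09 (SE, adjusted p = 2.68e-46). Tmem56 (3.32 ± 0.11) and Dnah8 (3.19 ± 0.12) were higher, in log2 fold change ± SE. Mrpl23 (3.34 ± 0.10) shares reads with Mrpl23-ps1, and their sum was at 0.21 ± 0.07, so the level of Mrpl23 alone is uncertain. Rtn4r, which encodes the Nogo receptor, had 6 counts over the 8 libraries, 337-fold lower, with a counting interval of 155 to 919. Rpl31-ps8 (0 counts, at least 1651-fold lower) and Eif4a-ps4 (23 counts, 891-fold lower, with a counting interval of 594 to 1405) are pseudogenes with near-identical copies, and without PWK_4 the mean of Eif4a-ps4 was 0.05 CPM in place of 0.0813. Trim12c, at -4.14 ± 0.09 summed with its copies, had 2 counts, both in PWK_3, 1377-fold lower, with a counting interval of 381 to 11373. In PWK 8905 genes passed the test, 4502 higher and 4403 lower. Of these 826 and 1118 were at least 2-fold apart. For 322 tested genes every library of the strain lay above all other libraries, and for 222 below.

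WSB hearts had more RNA of heat shock genes and less of antigen presentation genes. Among heat shock genes and chaperones, 11 of 14 measured members were higher and 3 did not pass the gene test, with Hsph1 at 221 ± 60.3 CPM (SD, n = 8) against 93.5 over the other strains, a log2 fold change of 1.28 ± 0.18 (SE, adjusted p = 2.47e-08). The near-identical pair Hspa1b (2.75 ± 0.41) and Hspa1a (1.81 ± 0.40) was higher, at 2.30 ± 0.40 in sum (camera adjusted p = 0.000229, and adjusted p = 0.997 with an estimated correlation). For MHC class II, 7 of 8 measured members were lower and 1 did not pass the gene test (8 lower when adjusted over the list alone), with H2-Eb1 (-5.09 ± 0.45), H2-Ab1 (-1.21 ± 0.26) and Cd74 (-0.80 ± 0.27) lower (camera adjusted p = 0.00698, and adjusted p = 0.997 with an estimated correlation). For MHC class I and antigen processing, 1 of 15 measured members were higher, 12 lower and 2 did not pass the gene test, with H2-D1 (-2.97 ± 0.19) lower. Summed with their relatives H2-D1 (-1.69 ± 0.18), H2-Q6 (-2.56 ± 0.36) and H2-Q7 (-2.50 ± 0.35) stayed lower, and H2-T22 was at 0.54 ± 0.12 (camera adjusted p = 0.000361, and adjusted p = 0.997 with an estimated correlation). Not summed, H2-T22 was lower than B6. For the interferon response, 1 of 26 measured members were higher, 12 lower and 13 did not pass the gene test (2 higher and 13 lower when adjusted over the list alone), with Ifi27 (0.49 ± 0.10) higher and Gbp3 (-1.99 ± 0.24), Rsad2 (-1.32 ± 0.15) and Xaf1 (-0.88 ± 0.13) lower (camera adjusted p = 0.00934, and adjusted p = 0.997 with an estimated correlation), and that call was lost with a mean log2 CPM of at least 1 as the filter (adjusted p = 0.0669). For cardiac stress and fetal genes, 1 of 15 measured members were higher, 8 lower and 6 did not pass the gene test, with Mybpc2 (-1.52 ± 0.10) and Acta1 (-1.03 ± 0.20) lower (camera adjusted p = 0.0356, and adjusted p = 0.958 with an estimated correlation). That call was lost without WSB_6 (adjusted p = 0.0775), WSB_7 (0.0513) or WSB_9 (0.0579). Myh7 (-1.60) has the copy Myh6, and their sum, 32050 CPM in WSB, is nearly all Myh6 and cannot tell whether Myh7 changed. Acta1 was higher than B6 where B6 was the reference, and Actn1 (0.19 ± 0.06) did not pass without WSB_1 (0.09 ± 0.06, adjusted p = 0.19). For B and plasma cell markers, 8 of 12 measured members were lower and 4 did not pass the gene test (9 lower when adjusted over the list alone), with Ighm (-1.93 ± 0.60) lower (camera adjusted p = 0.0278, and adjusted p = 0.997 with an estimated correlation). Without WSB_6 that list did not pass (adjusted p = 0.0571). Against B6 alone Myh7, Ifi27 and Ighm did not pass (adjusted p from 0.137 to 0.801), nor did Ifi27 without PWK (0.278) or Cd74 without B6 (0.0589) in the reference.

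A pair of WSB calls rested on WSB_1, which stood apart from the other WSB libraries in 19 of the reported values. For endothelial markers, 9 of 13 measured members were higher and 4 did not pass the gene test, with Esam (0.44 ± 0.08), Emcn (0.41 ± 0.09) and Eng (0.38 ± 0.07) the largest (camera adjusted p = 0.0319, and adjusted p = 0.997 with an estimated correlation). Without WSB_1 the adjusted p was 0.320, and without WSB_4 it was 0.0547. For ketone body and branched-chain amino acid metabolism, 1 of 16 measured members were higher, 7 lower and 8 did not pass the gene test, with Bcat2 (-0.65 ± 0.06), Acat1 (-0.50 ± 0.07) and Mccc2 (-0.48 ± 0.07) lower and Bdh1 (0.42 ± 0.13) higher (camera adjusted p = 0.018, and adjusted p = 0.997 with an estimated correlation). Without WSB_1 the adjusted p was 0.145, and Bdh1 did not pass without 129 (0.167), B6 (0.0545) or PWK (0.133) in the reference. In WSB_1 Esam was at 130.7 CPM against 45.8 to 65.1 in the other WSB libraries, and Acat1 was at 138.9 CPM against 314 to 382.

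Cwc22, which encodes a splicing factor (ENSMUSG00000027014, chromosome 2, 77881159 to 77946375), was at 747 ± 162 CPM (SD, n = 8) against 11.8 in WSB, a log2 fold change of 6.0 ± 0.05 (SE, adjusted p = 2.86e-71). The retinoid transporter gene Abca4 (3.41 ± 0.07) and Cit (2.86 ± 0.09) were higher as well. Masp1, which encodes a protease of the lectin pathway of complement, was at 0.759 ± 0.255 CPM (SD, n = 8) against 11.2, a log2 fold change of -3.75 ± 0.16 (SE, adjusted p = 2.28e-29). Zfp738 had 0 counts and was at least 425-fold lower. Ly6c1 had 2 counts, both in WSB_1, 7442-fold lower, with a counting interval of 2060.1 to 61448, and Ly6c2 was lower too. Each is the other's near-identical copy, and their sum was still lower (-8.08 ± 0.22). Part of Ly6c1 also matches Ly6a, and with Ly6a in the sum the value was -0.35 ± 0.15, so a share of reads with Ly6a stays open. Summed with its copies Tgtp1 was lower (-2.42 ± 0.36), and Rpl12 did not pass (adjusted p = 0.495). In WSB 7455 genes passed the test, 4210 higher and 3245 lower. Of these 731 and 608 were at least 2-fold apart. For 58 tested genes every library of the strain lay above all other libraries, and for 63 below. Without WSB_1, 7119 genes passed, and 77.4% of the 7455 calls were kept.

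Wild-derived strains (Cast, PWK and WSB) were set against the classical strains, with the 8 strain means as replicates. Egf, which encodes epidermal growth factor (ENSMUSG00000028017, chromosome 3, 129677565 to 129755316), was at 0.71 CPM in Cast, 1.27 in PWK and 1.65 in WSB, and between 8.88 and 20.6 CPM in the classical strains. Its log2 fold change was -3.45 ± 0.31 (SE, adjusted p = 0.00805) in limma. Folr2, which encodes a folate receptor of tissue macrophages, was at 0.763 CPM or less in the wild-derived strains and at 4.73 CPM or more in the classical strains, at -3.31 ± 0.22 (SE, adjusted p = 0.00167). Tnfsf13b, which encodes the B cell survival factor BAFF, was higher at 1.89 ± 0.19 (SE, adjusted p = 0.0121), and Por, which encodes the electron donor of cytochromes P450, at 1.06 ± 0.10 (SE, adjusted p = 0.00946). Each of these genes had no overlap between the 3 and the 5 strain means. Amd2 (6.46 ± 0.41) has the copy Amd1 and is uncertain, and AK010878 (1.24 ± 0.15) was also higher but has the copy Gm20604. Ubxn10 (-2.89 ± 0.28), Pon3 (-2.04 ± 0.21), Fxyd6 (-1.92 ± 0.24), Slfn2 (-1.68 ± 0.22), Mzt1 (-1.01 ± 0.09), Pex7 (-0.81 ± 0.09) and Pdxdc1 (-0.65 ± 0.07) were lower, as was Paqr7 (-0.82 ± 0.11), which did not pass without Cast_1, Cast_5 and Cast_6 (adjusted p = 0.0916). Only 23 genes passed, 4 higher and 19 lower, while 2697 of 16425 had an unadjusted p under 0.05. For 10.8% of genes the strain means did not overlap, where chance gives 3.57%. Strain kinship was not modelled, and the count rose to 872 without WSB.

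Over the 41 lists with at least 3 measured members and the 8 strains, 46 of 328 camera tests passed an adjusted p of 0.05. With the correlation estimated for each list 0 passed (limma's camera, lowest adjusted p = 0.248), and 16 had an unadjusted p under 0.05. The median estimated correlation of the called lists was 0.507, against the preset 0.01. In fry, which asks whether a list's genes move in the same direction on balance, 44 of the 46 passed in the same direction, and fatty acid oxidation (adjusted p = 0.0616) and the TCA cycle (0.12) in 129 did not. It does not compare a list with other genes and was not run on random labels. Where most genes differ among strains, it cannot back the camera calls. Random strain labels gave at least 46 camera calls in each of 99 draws, with a median of 79 and a highest of 107. No called list had a median or mean of the other sign from its test. Leaving out 1 library at a time, 38 of the 46 calls were kept whichever of the 63 was left out, and 8 were not.

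**Figure D5:**
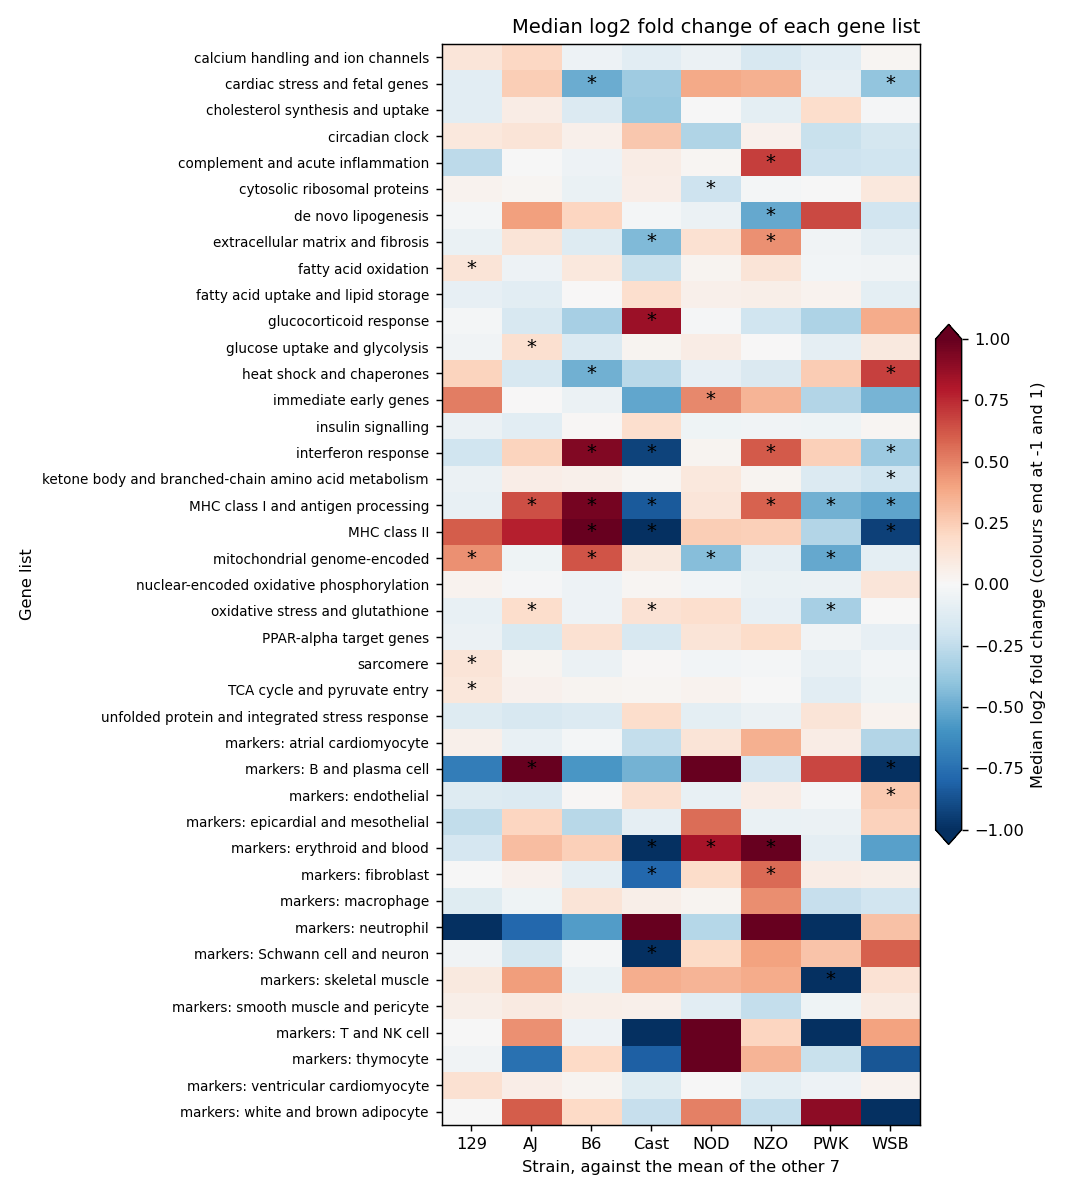
Median log2 fold change of each gene list (y axis) in each strain against the mean of the other 7 (x axis), with colours ending at -1 and 1 and an asterisk at a camera adjusted p under 0.05. B6 is higher and Cast lower for interferon response, MHC class I and MHC class II genes, and 46 squares carry an asterisk.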

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

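The tests of copies, of transcript length, of mixed samples and of cell type shares were chosen after the results were seen, and the test of GC content was written before. Within each strain a library was set apart where its gap to the nearest other, over the range of the strain, passed Dixon's critical value. This held in 42 of 266 groups (15.8%), where chance gives about 1 in 20, and 19 of the 42 were in WSB_1.

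In WSB_1 values stood apart as follows, with the range of the other WSB libraries in brackets and all in CPM. Higher were Cwc22 at 1141 (634 to 726), Rpl12 at 206.6 (99.4 to 119), Cit at 34.16 (14 to 19.2), Actn1 at 52.42 (29.6 to 37.4) and Ifi27 at 32.4 (11.6 to 14.5). Also higher were Rsad2 at 6.776 (2.87 to 4.47), Xaf1 at 9.369 (3.21 to 5), Esam at 130.7 (45.8 to 65.1), Emcn at 92.27 (29.8 to 43.5) and Eng at 367.2 (145 to 197). Of MHC genes, H2-D1 at 26.32 (6.36 to 7.47), H2-Ab1 at 6.441 (2.9 to 3.7) and Cd74 at 24.96 (14.8 to 19.3) were higher. Lower were Acat1 at 138.9 (314 to 382), Mccc2 at 20.19 (39.4 to 45.6), Glo1 at 46.73 (76 to 89.8) and Nnt at 117.9 (634 to 721). Ly6c1 was at 0.05577 CPM in WSB_1 and at 0 in the others, and the TMM factor was 1.159 against 0.962 to 1.045.

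In NZO_8 the TMM factor was 1.08 against 0.935 to 0.986, and CPM values stood apart for C4b at 313.3 (38.9 to 92.1), C1s1 at 138.7 (59.8 to 67.2), C3 at 1555 (235 to 366) and, lower, Pccb at 21.64 (27.7 to 31.2). NZO_5 was high for Iigp1 at 78.5 (11.5 to 27.8) and Nlrc5 at 13.95 (2.06 to 7.28), NZO_6 for Cfd at 5.828 (0.359 to 2.08), and NZO_1 had the only count of Zfp607 (0.03008 CPM). In Cast_1 Mt2 at 81.4 (10.4 to 37.5) and Hmox1 at 129.6 (10.8 to 28.1) were high. Cast_8 had Rpl9-ps6 at 0.2986 (0 to 0.0905) and Cast_6 had Tgtp2 at 0.09814 (0 to 0.038). PWK_3 had Tmem56 at 36.97 (22.4 to 29.1) and the only counts of Trim12c (0.05437 CPM), PWK_6 had Acta1 at 521.1 (147 to 274) and PWK_1 had mt-Atp8 at 1796 (266 to 922). AJ_1 had a total of 42.95 M counts (28.4 to 34.4 in the other AJ libraries), and AJ_3 was low for Trabd2b at 29.23 (33.6 to 37.5) and Nnt at 626.6 (721 to 768). Single values were Cryab at 964.5 (599.8 to 763) in 129_7, Hrasls at 1.896 (2.72 to 3.42) in NOD_3 and Acta1 at 440.8 (127 to 264) in WSB_7.

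Wide strain ranges in genes with a near-identical copy differed by class. Among 722 genes with strain means at least 2 log2 units apart 167 had such a copy, and summing with the copies took their median range from 3.58 to 1.93 log2 units. For 21 ribosomal protein genes and pseudogenes the median fell from 6.15 to 0.308, with all 21 under 1, which fits reads that move between copies by strain, and for mt-Co2 and mt-Nd4l, at a larger summed range of 1.04, shared reads may explain most of their own range. For the other 144 genes the median fell from 3.20 to 2.10, just above a bound of 2 that was set after the values were seen. Shared reads may account for part of these ranges but not for the whole as a class, though 34 of the 144 sums were under 1. Strain variants against the reference were not tested and stay open.

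In WSB_1 long transcripts were lower on average than in the other WSB libraries: over 11278 protein-coding genes its deviation changed by -0.351 log2 units per doubling of transcript length, against -0.140 in NOD_8, the next of the 62 other libraries. The rank correlation was weaker in WSB_1 (-0.346) than in NOD_8 (-0.579) and 129_3 (-0.526), and the trend took 15.0% of the mean square deviation of WSB_1. Of 22 lists with a median in WSB_1 outside all other libraries 16 stayed outside without the trend (fatty acid oxidation at -1.14), against lost long transcripts as the whole cause. Against GC content as the whole cause the slope was -0.301 with GC in the model. Against RNA of another strain, genes near 0 in the other WSB libraries were at 0.585% of the level of other strains. Endothelial exceeded fibroblast markers by 0.636 log2 units. This gap cannot exclude a lower share of cardiomyocytes, since other cell types need not rise equally. Ventricular (-0.37), atrial (0.64), epicardial (1.47), Schwann cell (1.17) and erythroid (1.37) medians also lay outside all other libraries, while others such as fibroblast (0.23) lay inside. Without the length trend the atrial and erythroid medians lay inside. Degradation may underlie the trend of -0.351, while the cause of the rest, shares of cell types included, is open. No other biological explanation was tested.

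Cast_1, Cast_5 and Cast_6 had more Fkbp5 and less Col1a1 and Cd74 than the other Cast libraries. Beside this, in log2 units from the Cast mean, the neutrophil median was 1.74 in Cast_5 and 2.17 in Cast_6, their B cell medians were -1.47 and -1.03, and the skeletal muscle median was 1.72 in Cast_1, the adipocyte median was -2.40 in Cast_5, and heat shock medians were -0.33, -0.34 and -0.43 in the 3 and above 0 in the other 4. Genes near 0 in the other Cast libraries were at most at 0.444% of the level of other strains, which argues against RNA of another strain. This test cannot detect other tissue from a Cast mouse, and the skeletal muscle median was high in Cast_1. The largest length slope in size, 0.0218, lay inside the range of the others, against lost long transcripts. Endothelial exceeded fibroblast markers by at least 0.278 log2 units, so the 2 sets of markers did not fall equally. This gap cannot exclude a lower share of all cells other than cardiomyocytes, since such cell types need not fall equally. Changes in single cell types, sex, stress and the day of collection are open and were not tested as causes here. These libraries may thus differ in biology or in handling.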

How the results depend on the processing

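The alternatives without WSB_1, without Cast_1, Cast_5 and Cast_6, without each single library, without each strain of the reference and with copies summed were chosen after seeing the data, and the others before. Counts of differing genes stayed within 1.5 times the reported count under all alternatives for the test over all strains (10757 to 16343) and the pairwise median (5209.5 to 7400.5). The scaling alternative shifted the median of all genes by at most 0.005 log2 units. For single strains only a minimum change of 0.5 log2 units (glmTreat) moved the count further: 914 genes in 129, 1121 in AJ, 1013 in B6, 3152 in Cast, 1122 in NOD, 1328 in NZO, 2560 in PWK and 1503 in WSB, since it asks for more. With limma on the variance-stabilised values fewer genes were higher than lower in 129 (2560 and 2740), Cast (4867 and 5089), PWK (4261 and 4516) and WSB (3483 and 3834), where the reported fit has more that are higher. The order also turned in 129 with B6 as the reference, and in Cast and PWK under several alternatives, so no balance of directions is claimed there.

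Wild-derived calls (23) became 42 with no filter, 42 without Cast_1, Cast_5 and Cast_6, 7 at an adjusted p of 0.01 and 9795 with mice as replicates (edgeR). Leaving out each strain gave 18 (B6) to 872 (WSB). The cause was not tested. List calls (46) became 0 with an estimated correlation and 109 in fry, 44 to 51 without single libraries, 58 with no filter (13 gained, 1 lost), and 39 with a mean log2 CPM of at least 1 as the filter (38 kept, 5 lost, 1 gained, and 3 with under 3 members left).

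Of 3496 values for named genes 3381 kept direction and side of the threshold, 91 lost the call (56 of these with glmTreat), 4 gained it and 20 reversed. The 20 reversed with B6 as the reference, by the construction of that contrast. In 129 this was mt-Nd4l (-0.14). In AJ it was Pfkp (0.12), H2-Q6 (-0.80), H2-Q7 (-1.36) and Nlrc5 (-0.31), in Cast Hba-a1 (0.10), and in NOD Rpl19 (0.10), Rpl27 (0.12), mt-Co2 (-0.58) and mt-Nd4l (-0.87). In NZO it was Iigp1 (-0.66), Ifi44 (-0.39), Rsad2 (-0.47), Nlrc5 (-0.43), H2-D1 (-0.17), Glo1 (0.011) and Nnt (0.30), in PWK Acta1 (0.94), and in WSB Acta1 (0.89) and H2-T22 (-0.46). Trac in NOD reversed without NOD_5 (-0.10), and was 1.133 without NOD_3.

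Libraries with the same replicate number in different strains were weakly more alike: over 199 pairs with the same number in different strains the mean r of deviations was 0.042, against -0.005 for different numbers (permutation test within strains, p = 1e-04, the smallest that 9999 shuffles can give). Of 63 libraries 14 were closest to one with their own number, and a median of 7 in the shuffles (permutation test, p = 0.0306). Both tests were chosen after the values were seen. On PC2 of these deviations replicates 1 to 4 were below 0 and 5 to 8 above in each of AJ, B6 and NZO. In 129, NOD and Cast 1 library of each was out of place, and PWK and WSB did not follow. What the numbers stand for is not in the labels. A replicate block gave 14712 genes over all strains, 4972 in 129, 6407 in AJ, 5189 in B6, 9815 in Cast, 5424 in NOD, 6660 in NZO, 8817 in PWK, 7378 in WSB and 49 list calls, 46 of them kept. Depth limits genes near the floor of 3 counts, and no fitted fold change is given for a strain at that floor. Such a strain still enters the reference of the others. Leaving each strain out of the reference in turn kept 227 of 242 named calls, and 10 lost the call or reversed and in 5 the log2 fold change shrank by more than 50%.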

Other observations

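The tests of single libraries and the genes in the next paragraphs were chosen after the values were seen, while the tests of other splits, of Fkbp5 and of Dbp were written before. In NOD hearts T cell genes were high in 1 library. Lck, which encodes a T cell kinase, was at 33.1 CPM in NOD_5 and at a mean of 0.668 in the other NOD libraries, so its log2 fold change was 4.52 ± 0.44 (SE) with NOD_5 and 1.72 ± 0.37 (adjusted p = 0.00013) without. Cd3e had a mean of 1.24 CPM with NOD_5 and 0.407 without, and stayed higher (1.56 ± 0.33). Trac was higher with NOD_5 (1.20 ± 0.35) and not without (-0.10 ± 0.34, adjusted p = 0.858). The T and NK cell list had 6 of 7 members higher in NOD (camera adjusted p = 0.0757) and the thymocyte list 4 of 4 (0.255). In NZO the neutrophil gene S100a9 was at 87.4 CPM in NZO_8, and without that library its log2 fold change went from 4.29 ± 0.46 to 0.79 ± 0.41 (adjusted p = 0.123). Lcn2 followed the same pattern (1.28 ± 0.36 with NZO_8 and 0.17 ± 0.36 without).

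Lipid genes differed by strain without a call of their list. Sqle, which encodes squalene epoxidase, was at 3.56 ± 0.64 CPM (SD, n = 8) in PWK (1.35 ± 0.11, adjusted p = 7.5e-17). For cholesterol synthesis and uptake, 14 of 19 members were lower in Cast (adjusted p = 0.0757) and 9 higher in PWK (0.0719). Plin1, which coats lipid droplets of adipocytes, was lower in WSB (-2.66 ± 0.60, adjusted p = 0.000235). In PWK it was higher (1.15 ± 0.37, adjusted p = 0.00749) but not without PWK_3 (0.0697) or PWK_4 (0.0771). Adipoq was at 1.24 CPM in WSB, at 0.764 without WSB_1, and reached 20.5 CPM in PWK_2. Adipocyte markers had 6 of 12 members lower in WSB (adjusted p = 0.0716). The macrophage gene Cd163 was higher in Cast (1.06 ± 0.11, adjusted p = 9.26e-13), and 10 of 13 macrophage markers were higher in NZO (list adjusted p = 0.0593).

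The other lists that passed in no strain had these lowest camera adjusted p-values: calcium handling 0.0646 in 129, smooth muscle and pericyte 0.0668 in NZO, and ventricular cardiomyocyte 0.078 in 129. For marker and signalling lists they were epicardial 0.125 in NOD, nuclear oxidative phosphorylation 0.142 in WSB, circadian clock 0.149 in NOD, neutrophil 0.164 in Cast, and insulin signalling 0.173 in Cast. The highest were atrial cardiomyocyte 0.188 in WSB, unfolded protein response 0.245 in PWK, PPAR-alpha targets 0.313 in B6, and fatty acid uptake 0.46 in WSB. None of the 10 lung and airway markers was among the tested genes. In Cast_1 the skeletal muscle gene Atp2a1 was at 17.9 CPM, against 6.01 or less in every other library.

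Among calls of at least 2-fold, the percent that were lower was 45.9 in 129, 38.1 in AJ, 38.3 in B6, 58.1 in Cast, 26.1 in NOD, 38.7 in NZO, 57.5 in PWK and 45.4 in WSB. In NOD 787 of these calls had a mean log2 CPM under 1 (24.7% lower). The share was 27.0% of 126 at 1 to 3, 38.5% of 78 at 3 to 6 and 30% of 10 above 6.

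Within strains, Dbp was set against Arntl, clock genes that peak at opposite times, to ask whether the time of collection varied. Over the 63 libraries the deviations from the strain means had r = -0.892 and rho = -0.889 (permutation p = 1e-05 for each, the smallest that 1e+05 resamples can give, and 2e-05 adjusted over the 2 relations). Without the 2 libraries farthest in Dbp (B6_7 and Cast_7) r was -0.844, and it was below 0 within 8 of 8 strains (-0.981 to -0.178). Different collection times may therefore add to the spread within strains. Dbp also differed between some strains, at 8.06 to 21.9 CPM in AJ and 5.02 to 13.6 in NZO against 0.994 to 4.52 in NOD. Other strains ranged widely, such as 1.38 to 81.4 CPM in B6, and the circadian clock list passed in no strain. Collection time may thus also differ between strains, and its effect cannot be told apart from strain here.

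Fkbp5 was set against the median of MHC class II genes to ask whether glucocorticoid level lowers antigen presentation, a relation that had been seen within Cast beforehand. The deviations had r = -0.288 (permutation p = 0.057, also 0.057 adjusted over the 2 relations) and rho = -0.301 (p = 0.031). Without the 2 libraries farthest in Fkbp5 (129_6 and Cast_1) r was -0.284. It was -0.820 in Cast, -0.717 in 129, -0.408 in B6, -0.335 in NOD, -0.266 in WSB, -0.229 in PWK, 0.0193 in AJ and 0.600 in NZO, and -0.035 over all strains but Cast. The pooled value rests on Cast, and an effect of glucocorticoid cannot be told apart from another difference among the Cast libraries with these samples.

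Random strain labels were drawn 99 times and tested in the same way, so the real labels are 1 of 100 splits. The real count was above every other split for the test over all strains (14837, highest other 1433), 129 (5071, 920.0), AJ (6438, 3168), B6 (5225, 707), Cast (9886, 407), NOD (5527, 816), NZO (6739, 536), PWK (8905, 557) and WSB (7455, 680.0). It was also above for the pairwise median (7098.5, highest other 16) and the median share of variance (0.443, 0.051), so chance can be excluded for these. Of the 56 splits of the strains into 3 and 5, only the real one reached 23 genes (highest other 6), and 1 of 56 is the smallest share possible. The next splits, with 6, 5 and 4 genes, all held Cast and PWK, and kinship was not modelled. The splits therefore cannot tell a difference of wild-derived strains from one that rests on Cast and PWK. For the list tests all 100 splits gave at least 46 calls (highest other 107), so chance cannot be excluded for the number of list calls. The preset correlation of 0.01 lies below the median estimate of 0.507, which may add calls under any labels.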
